A study of Saccharomyces cerevisiae with 142 samples.

How the data were processed

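RNA from budding yeast (Saccharomyces cerevisiae) was measured on 142 Affymetrix expression arrays that make up 9 time courses in 6 groups. Per the labels, cdc14-3 and cdc15-2 (1 course each) were grown in rich medium with dextrose, arrested with alpha factor at 25 °C and released at 37 °C. The arrays of the other 4 groups are marked in their labels as re-analysed by the authors, and come from earlier studies. In those, small unbudded cells were collected by elutriation, a sorting of cells by size in a centrifuge. Wild type at 30 °C, the cyclin mutant and the cdc20 mutant (2 courses each) were followed in rich dextrose medium with 1 M sorbitol, and wild type at 37 °C (1 course) in prewarmed rich dextrose medium. Cells of cdc14-3 and cdc15-2 were collected on filters and frozen, and their RNA was extracted with acid phenol. RNA protocols are worded differently for the other groups, so array series and RNA work go with group.

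The deposited values are processed probe-set intensity values on a linear scale, which range from 22.2 to 35171. The authors name the affy package for their processing; its version, and the summary and normalization method, are not given in the sources used here. Array medians lay between 1056 and 1362, so the arrays had been brought to similar distributions, and quantile normalization of all arrays together moved the median of an array by at most 0.22 on the log2 scale. The plan made before the data were examined had taken the values to be on a log2 scale already. They were not, so the log2 was taken first, with a pseudocount of 0.

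The table held 5900 probe sets, of which 184 were controls, 218 others carried no gene name and 5498 were named for 1 gene. Names were matched by gene identifier to the reference table, which updated 12 symbols. For the 47 genes with several probe sets the probe set with the highest mean over all arrays was kept, which left 5449 genes. Columns left unused numbered 0. The number of arrays limits the precision of every value.

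A correction was made after the data were seen. In the 14 arrays of wild type at 30 °C, replicate 2, the values as deposited had a Pearson correlation of 0.0461 across probe sets with replicate 1 of the same group, and between 0.0461 and 0.0582 with the other courses, while the other courses had 0.889 to 0.987 among themselves. Correlations across probe sets do not treat genes as replicates; they check the order of the values. Moving the values up by 1 probe set raised the correlation with replicate 1 to 0.996, and no other move of up to 10 probe sets in either direction gave more than 0.0494. The move was found on the odd-numbered probe sets, where the second best of all moves reached 0.0817, and gave 0.996 on the even-numbered ones. The values of these 14 arrays were therefore used 1 place up from where they were deposited. This displacement is inferred from the values and is stated by no label. The value left over at the first probe set grew with sampling time from 26.8 at 38 min to 290.0 at 262 min; its meaning is not known and it was not used. All results that involve wild type at 30 °C were also computed with the values as deposited, and without this course.

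Tests used limma 3.58.1 and splines 4.3.3 in R 4.3.3, with figures drawn by matplotlib 3.10.9 and numpy 2.4.6, and p-values adjusted by the Benjamini-Hochberg method over the 5449 genes. The choices in this and the next 4 paragraphs, the gene lists and the alternatives were made before the data were examined, except where stated. Change over time within a group was an F-test of a natural cubic spline of time with 5 degrees of freedom and an intercept per course, called at an adjusted p under 0.05 and a fitted range of at least 1 on the log2 scale. Periodic expression was an F-test of a cosine and a sine with an intercept and a linear trend per course, called at an adjusted p under 0.05 and a fitted peak-to-trough of at least 1.5-fold. The period of a group was the one between 60 and 140 min, in steps of 5, that fitted the 120 measured cell cycle list genes best. The same test on samples taken at least 1 period after the first sample of a course was meant to ask whether a pulse came again. It was run where at least 8 arrays and 1 full period remained. A first pulse that comes late in a course can also fall in this window.

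Between groups the replicate was the time course, and each gene had 1 value per course. The late level was the mean log2 intensity from 100 min to the end of the course. The last sample came at 254 or 262 min in wild type at 30 °C and the cyclin mutant, and at 300 or 360 min in cdc20. It came at 225 min in wild type at 37 °C, 240 min in cdc14-3 and 180 min in cdc15-2, so the windows are unequal. The oscillation size was the fitted log2 peak-to-trough at the period of the group, so the sides of a comparison were fitted at unlike periods. All 9 courses entered 1 limma fit with 6 group means, called at an adjusted p under 0.05. It has 3 residual degrees of freedom, from the 3 groups with 2 courses, beside 4.29 prior degrees of freedom for the late level and 3.10 for the oscillation size. Groups with 1 course (wild type at 37 °C, cdc14-3 and cdc15-2) are assumed to vary like the others. cdc14-3 and cdc15-2 were also compared at their 16 shared times from 0 to 180 min with time as a factor, called at an adjusted p under 0.05 and at least 1.5-fold. The p-values measure only the spread between these samples: that of arrays around the fitted curve within a group or a matched pair of courses, and that of courses between groups. They do not extend to other cultures of the mutants with 1 course.

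A total of 17 gene lists was fixed, 7 of them for cell cycle phases; the results of 1 of these 7 are not reported here. The reported cell cycle lists are SBF targets and bud emergence, MBF targets and DNA replication, core histones, S/G2 regulators and chromosome segregation, the CLB2 cluster, and Mcm1 early cell cycle box genes. The others were pheromone response and mating, alpha-cell markers (transcripts of the other mating type), single-copy ribosomal proteins, ribosome biogenesis, Hsf1 heat shock, Msn2/4 general stress, glucose-repressed, galactose, phosphate starvation and DNA damage genes. Listed genes without a probe set of their own were left out. Shifts of whole lists in late level were tested with limma's camera at its preset correlation between genes of 0.01, and again with an estimated correlation. The phase of a list is the circular mean of its periodic members' peak times and has no test.

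The genes named were chosen by rule: the cell cycle regulators and the genes the mutants lack, in every group; the 10 genes with the largest peak-to-trough of each group; the 10 largest rises and falls per comparison of levels, where every course of a group lay beyond every course of the other (or at least 14 of 16 times went the same way); up to 4 members of each list with the smallest adjusted p; and the 10 cell cycle list genes with the largest loss and gain of oscillation. Values of single genes are log2 intensities or log2 differences, with the standard error of the fit after the ± sign.

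Alternatives were quantile normalization, leaving out the dimmest 25% of genes, leaving out samples before 30 min, a spline with 4 degrees of freedom, no minimum range, fold or peak-to-trough, periods 10 min shorter and longer, a quadratic trend, late levels from 140 min or over all samples, the SD over time in place of the peak-to-trough, matched times from 60 min, the replicate number as a block, an estimated correlation, phases over all members of a list, and leaving out each course of the 3 groups with 2. The procedures were tested on simulated data with 200 changed genes. The periodic test called 91% to 100% of 2-fold changes and the change test 83% to 95%. The late level test called 60% to 86% of 2-fold and 92% to 100% of 4-fold changes, the oscillation size test 74% to 88% and 95% to 99%, and the matched test 100%. At most 13 unchanged genes were called. The simulated scatter was independent between arrays, courses and genes, and the periodic test was given the true period. Real courses can share scatter and their period was chosen from the data, so these rates need not hold for the real data.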

Results

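The SBF targets, which drive budding, changed over time in 14 to 18 of 18 members in the 6 groups. The MBF targets, which drive DNA replication, changed in 24 to 29 of 31 members in 5 groups and in 6 of 31 in cdc14-3. The low count in cdc14-3 does not show that these genes stayed flat, as their mean climbed early there too. Most of them were periodic there when adjusted over the list alone, though not when adjusted over all genes. Whether the fitted curve misses a short pulse was not tested. The CLB2 cluster, which carries cells through mitosis, changed in 12 of 20 members in the cyclin mutant and 17 to 20 in the others. Values below are log2 intensities or log2 differences; the spread behind the p-values is described with the methods.

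Wild type at 30 °C, replicate 2, enters all results that involve this group with its values moved by 1 probe set. As deposited, these values had a correlation of 0.0461 with replicate 1, and after the move 0.996, with single arrays at 0.848 to 0.991. This displacement is inferred from the values and stated by no label, and every count below that rests on this group depends on it. With the values as deposited limma called 0 genes in each comparison of late levels or oscillation sizes. After the move it called 215 to 2803 genes in late level and 1 to 90 in oscillation size. Unadjusted p-values under 0.05 then numbered 310 to 3144. The comparisons of cdc14-3 and cdc15-2 with wild type at 37 °C hold no array of this group. They depend on the move only through the shared spread.

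**Figure D1:**
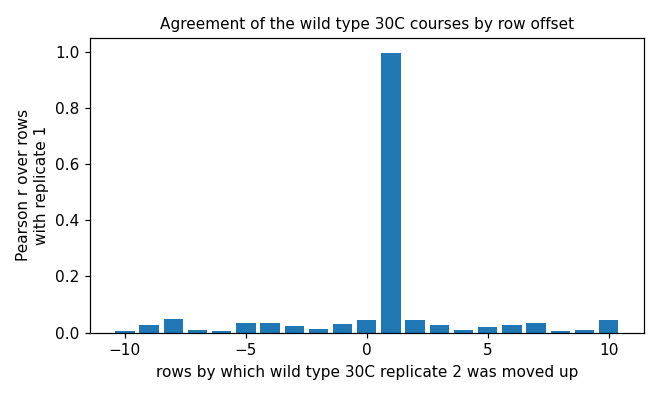
Pearson correlation between the course means of both replicates of wild type at 30 °C (vertical axis) after moving replicate 2 by the number of probe sets on the horizontal axis. A move by 1 brings the correlation close to 1, and all other moves shown leave it near 0.

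The 3'-to-5' difference of the TDH1 control probe sets, a sign of RNA integrity and labelling, moved with the groups and with time. Its mean was 1.00 ± 0.28 (SD over arrays) in cdc14-3, 1.97 ± 0.74 in cdc15-2 and 1.497 ± 0.22 in wild type at 37 °C. It was 2.15 ± 0.28 and 1.89 ± 0.17 in both courses of wild type at 30 °C, 1.98 ± 0.23 and 1.92 ± 0.23 in the cyclin mutant, and 2.98 ± 0.52 and 2.59 ± 0.83 in cdc20. Within a course it went from 0.79 at 20 min to 3.41 at 100 min in cdc20, replicate 2, and from 0.66 at 24 min to 3.04 at 132 min in cdc15-2, so changes over time there go along with it. The course means of the same difference for ACT1 (actin) lay between 0.41 and 0.58 in all 9 courses. Within some courses it moved with time as well. It went from 0.797 at 40 min to 0.319 at 340 min in cdc20, replicate 2, and from 0.781 at 30 min to 0.291 at 94 min in wild type at 30 °C, replicate 1. It was steadier in cdc14-3 and cdc15-2, with an SD over arrays of 0.044 and 0.038.

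Wild-type cells at 30 °C (2 courses, 28 arrays) expressed G1, histone and mitotic genes in turn. CLN2, a G1 cyclin that starts budding, reached 11.5 at 102 min (fitted range 4.37, adjusted p = 9.9e-07), and HTB2, a histone of newly made chromatin, 13.9 at 110 min (range 3.35). CLB2, the main mitotic cyclin, followed with 11.5 at 126 min (range 4.03, adjusted p = 1.5e-12). Then came CDC20, which starts anaphase, with 10.5 at 142 min, SIC1, the inhibitor that ends mitosis, with 10.96 at 158 min, and DSE2, a daughter cell wall gene, with 12.7 at 182 min. HSP12, a membrane stress protein, had its highest value of 14.9 at 30 min (range 5.16), while NIP7 and RPF2, ribosome assembly factors, reached 13.2 and 12.7 at 70 min.

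Of 5449 genes, 1963 (36.0%) changed over time in limma's F-test, and 709 were periodic at the group's period of 110 min. TOS6, a wall mannoprotein, had a peak-to-trough of 2.60 ± 0.55 (adjusted p = 0.00247), and PCL1, a G1 cyclin, 2.58 ± 0.47. RNR1, which makes DNA precursors, had 2.47 ± 0.51, MCD1, a cohesin, 2.39 ± 0.46 and YOX1, a repressor of early cell cycle genes, 2.29 ± 0.44. Periodic calls covered 17 of 18 SBF targets, 30 of 31 MBF targets and 7 of 7 histones. They also covered 10 of 13 S/G2 genes and 6 of 9 Mcm1 genes (8 when adjusted over the list alone). The CLB2 cluster had 5 of 20 periodic members (2 when adjusted over the list alone), although 19 of 20 changed over time; CLB2 itself had 1.30 ± 0.56 (adjusted p = 0.136). From 110 min after the first sample, 155 genes were periodic, 111 of which were periodic over the whole course, among them CLN2 (1.21, adjusted p = 0.000803). This later window held 12 of 18 SBF targets, 21 of 31 MBF targets (22) and 19 of 20 CLB2 cluster genes, but 0 of 7 histones. CLB2 was at 1.22 (adjusted p = 0.0143), SWI5, a daughter-gene activator, at 1.31 and DSE4, a wall glucanase, at 1.43. The window spans 120 min and opens near the highest CDC20 and SIC1 values given above. It can thus hold the end of a first mitotic pulse and does not by itself show a repeat. All 18 SBF targets, 27 of 31 MBF targets, 7 histones, 11 S/G2 genes and 7 Mcm1 genes changed over time. Ribosome biogenesis changed in 32 of 34 measured genes, stress genes in 20 of 21 and heat shock genes in 12 of 20. Without replicate 1, and likewise without replicate 2, 0 genes were periodic in limma, against 3060 with an unadjusted p under 0.05 with both.

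**Figure D2:**
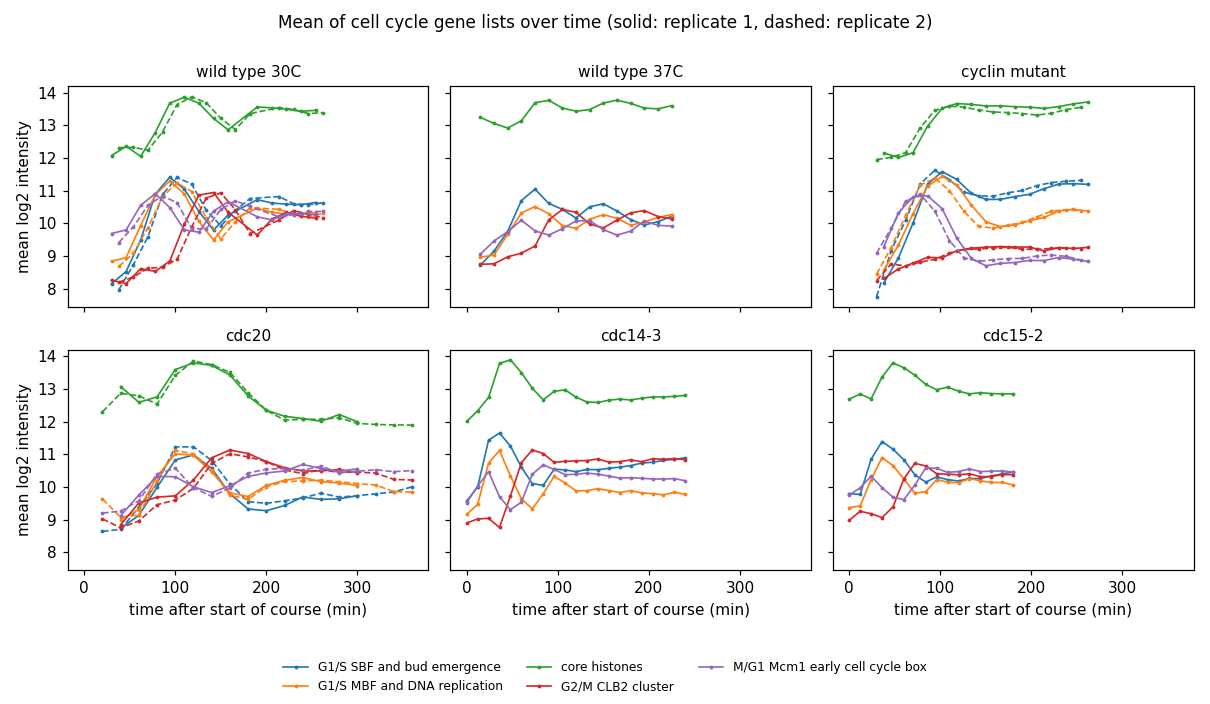
Mean log2 intensity of 5 cell cycle gene lists (vertical axis) over minutes from the start of the course (horizontal axis), with a panel for each group; solid lines are replicate 1 and dashed lines replicate 2. The means of the SBF and MBF targets climb early in all groups, and that of the CLB2 cluster climbs after them in all groups, least in the cyclin mutant.

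Wild-type cells at 37 °C (1 course, 15 arrays) began with high heat shock mRNA. SSA4, a heat-induced chaperone, was at 13.98 at 15 min (range 4.43, adjusted p = 2.5e-08) and BTN2, a protein sorting factor, at 14.3, while NIP7 and NOG1, ribosome assembly factors, climbed to 12.8 and 11.6 at 90 min. CLN2 reached 11.1 at 75 min (range 3.47, adjusted p = 0.000254), RNR1 12.9 at 75 min, CLB1, a mitotic cyclin, 11.1 at 105 min and DSE2 13.1 at 135 min (range 4.03, adjusted p = 3.9e-10). HUG1, a DNA damage gene, rose to 10.6 at 225 min, and PHO84, a phosphate importer, to 13.8 at 60 min.

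In this group 1769 genes (32.5%) changed in limma's F-test. They held 16 of 18 SBF targets (17 when adjusted over the list alone), 24 of 31 MBF targets, 1 of 7 histones and 6 of 13 S/G2 genes. Of later phases they held 18 of 20 CLB2 cluster genes and 4 of 9 Mcm1 genes. Outside the cell cycle they held 33 of 34 ribosome biogenesis, 12 of 20 heat shock and 20 of 21 stress genes. By limma, 0 genes were periodic at 85 min, against 396 with an unadjusted p under 0.05; adjusted over the list alone, 17 MBF and 9 SBF genes were. In the later 9 arrays, 22 genes were periodic, among them SVS1, a wall gene (1.03), SCW10, a glucanase (0.83), MCD1 (0.76), HOF1, which acts in cytokinesis (0.74), CDC20 (0.69) and SWI5 (0.60). The 22 include 6 CLB2 cluster (8 over the list alone), 4 MBF and 1 SBF (7) genes. This window opens near the highest CLB1 value given above, so it does not by itself show a repeat.

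The cyclin mutant (2 courses, 30 arrays), with all 6 B-type cyclin genes disrupted per its label, rose in G1 and replication genes while CLB2 stayed low. CLN2 reached 12.0 at 94 min (range 5.12, adjusted p = 1.6e-14) and RNR1 13.8, whereas CLB2 did not pass (range 0.56, adjusted p = 0.235). The pheromone genes MFA2 and FAR1, for a mating factor and a cell cycle inhibitor, went from 13.97 and 11.1 at 70 min to 9.03 at 254 min and 7.11 at 238 min. BTN2 climbed to 12.5 at 190 min and STI1, a chaperone helper, to 14.1 at 214 min.

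Change over time was called by limma for 2039 genes (37.4%) and periodicity for 519 at 140 min, the upper end of the periods tried, so a longer period is not excluded. YBR071W, a gene of unknown function, had a peak-to-trough of 2.82 ± 0.22 (adjusted p = 1e-08), TOS6 3.05 ± 0.45 and POL30, the replication clamp, 2.67 ± 0.37. The same value was 2.48 ± 0.25 for MSA2, a G1 regulator, 2.39 ± 0.29 for CDC21, of thymidylate synthesis, and 1.95 ± 0.25 for SWI4, the DNA-binding part of SBF. Periodic calls covered 13 of 18 SBF targets (16 when adjusted over the list alone), 29 of 31 MBF and 4 of 7 histone genes (5). Among the other lists they covered 7 of 20 CLB2 cluster, 9 of 9 Mcm1 and 10 of 20 heat shock genes (11). Change over time covered 18 SBF, 29 MBF, 7 histone and 11 S/G2 genes. It also covered 12 CLB2 cluster and 31 ribosome biogenesis genes. The later window spans 88 min, under 1 period, and was not tested. Without replicate 1 of the mutant 57 genes were periodic, and without replicate 2 154.

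Depleted of Cdc20, which releases cells into anaphase, the cdc20 mutant (2 courses, 32 arrays) brought mitotic genes up by 160 min. CLB2 reached 11.7 at 140 min (range 4.03, adjusted p = 4.7e-17), CLB1 11.6, SWI5 11.7 at 160 min and CDC5, the polo kinase of mitosis, 11.6. CLN2 peaked at 11.1 at 100 min, and CLN3, the most upstream G1 cyclin, rose to 13.2 at 360 min (range 3.14). HHT1, a histone, went from 13.8 at 120 min to 11.4 at 360 min. Samples after 300 min come from replicate 2 only, so each value at 360 min rests on a single array. The TDH1 3'-to-5' difference was 1.27 on that array, against 3.41 at 100 min of the same course. GAL1, galactokinase, went from 13.9 at 20 min to 8.91 at 280 min (range 4.72, adjusted p = 1.1e-21), and SIC1 did not pass with a range of 0.55.

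Change over time was called by limma for 3058 genes (56.1%) and periodicity for 220 at 140 min, again the upper end. RNR1 had a peak-to-trough of 2.24 ± 0.43 (adjusted p = 0.00279), PCL1 2.20 ± 0.54, MCD1 2.02 ± 0.40, CLN2 1.88 ± 0.41, POL30 1.86 ± 0.34 and YOX1 1.77 ± 0.38. Periodic members numbered 12 of 18 SBF (15 when adjusted over the list alone), 27 of 31 MBF (28) and 4 of 7 histone genes (6). There were 4 of 9 Mcm1 and 0 of 20 CLB2 cluster genes. Change over time covered 17 SBF, 27 MBF, 7 histone and 12 S/G2 genes. It also covered 17 CLB2 cluster, 33 ribosome biogenesis and 21 stress genes. After the first period 4 genes were periodic: PHO5, a phosphatase (1.59), ENB1, an iron importer (0.66), FMP23 (0.61) and SPL2, a phosphate regulator (0.60). Without replicate 1 of cdc20 0 genes were periodic in limma, whole course and later window alike, and without replicate 2 1 was, over the whole course. With both, 1556 genes had an unadjusted p under 0.05 over the course and 595 in the later window.

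In cdc14-3 (1 course, 21 arrays), whose heat-sensitive protein is the phosphatase that reverses mitotic phosphorylation, G1 genes peaked early and mitotic genes after them. CLN2 reached 11.7 at 36 min (range 2.00, adjusted p = 0.00499), and HTB2 13.8 at 48 min (range 3.80). CLB1 reached 11.6 at 60 min (range 4.37, adjusted p = 8.1e-07), CLB2 10.6 at 72 min and CDC20 10.97 at 84 min, while SWI5 had its highest value, 11.2, at 204 min. CTS1, the chitinase of cell separation, went from 12.4 at 0 min to 9.68 at 84 min. FIG1 and PRM2, of cell fusion in mating, went from 13.9 and 12.6 at 0 min to 9.66 and 8.55 at 240 min after release from alpha factor.

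Limma called 1238 genes (22.7%) as changing over time, and 462 when samples before 30 min were left out. Among them were 14 of 18 SBF targets, 6 of 31 MBF targets (1 when adjusted over the list alone), 6 of 7 histones and 7 of 13 S/G2 genes. The CLB2 cluster changed in 20 of 20 members and Mcm1 genes in 3 of 9. Other lists gave 18 of 20 pheromone, 25 of 34 ribosome biogenesis (26) and 15 of 21 stress genes (16). The mean of the CLB2 cluster was 8.76 at 36 min, 11.13 at 72 min and 10.84 at 240 min. By limma, 0 genes were periodic at 75 min, against 381 with an unadjusted p under 0.05, and 0 in the later 14 arrays, against 131; adjusted over the list alone, 23 MBF genes were periodic over the course.

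In cdc15-2 (1 course, 16 arrays), whose heat-sensitive protein is a kinase of mitotic exit, CLN2 reached 11.1 at 36 min (range 2.41, adjusted p = 0.00243) and YOX1 12.0 (range 4.40, adjusted p = 4.1e-06). CLB2 reached 10.3 at 72 min (range 1.98, adjusted p = 3.3e-06), CHS2, which builds the septum, 12.0, and SIC1 and NIS1, a bud neck gene, 10.3 and 11.3 at 96 min. DSE2 went from 10.6 at 0 min to 8.25 at 108 min, and FIG1 from 13.7 at 0 min to 9.55 at 180 min.

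Change over time was called by limma for 1031 genes (18.9%) and periodicity for 329 at 140 min, the upper end. With samples before 30 min left out these counts were 327 and 218. YPS3, a wall protease, had a peak-to-trough of 2.50 ± 0.31 (adjusted p = 0.00143), TOS6 2.48 ± 0.53, PHO5 2.26 ± 0.29, and NRM1, the repressor of MBF targets, 2.17 ± 0.39. SUR7, of membrane compartments, had 2.03 ± 0.49, CLB1 1.67 ± 0.30, CHS2 1.46 ± 0.25 and CLB2 1.33 ± 0.19 (adjusted p = 0.00238). Periodic members numbered 16 of 20 CLB2 cluster (18 when adjusted over the list alone), 6 of 7 histone, 10 of 18 SBF (12) and 1 of 31 MBF genes. There were also 5 of 20 pheromone (11) and 7 of 21 stress genes (17). Changing members numbered 16 SBF, 28 MBF, 4 histone and 7 S/G2 genes. The CLB2 cluster gave 19, and the other lists 19 pheromone, 2 Mcm1, 7 ribosome biogenesis (0 over the list alone) and 18 stress genes. The course is 180 min long, so 1 period of 140 min and its trend are hard to part, and the later window of 4 arrays was not tested.

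**Figure D3:**
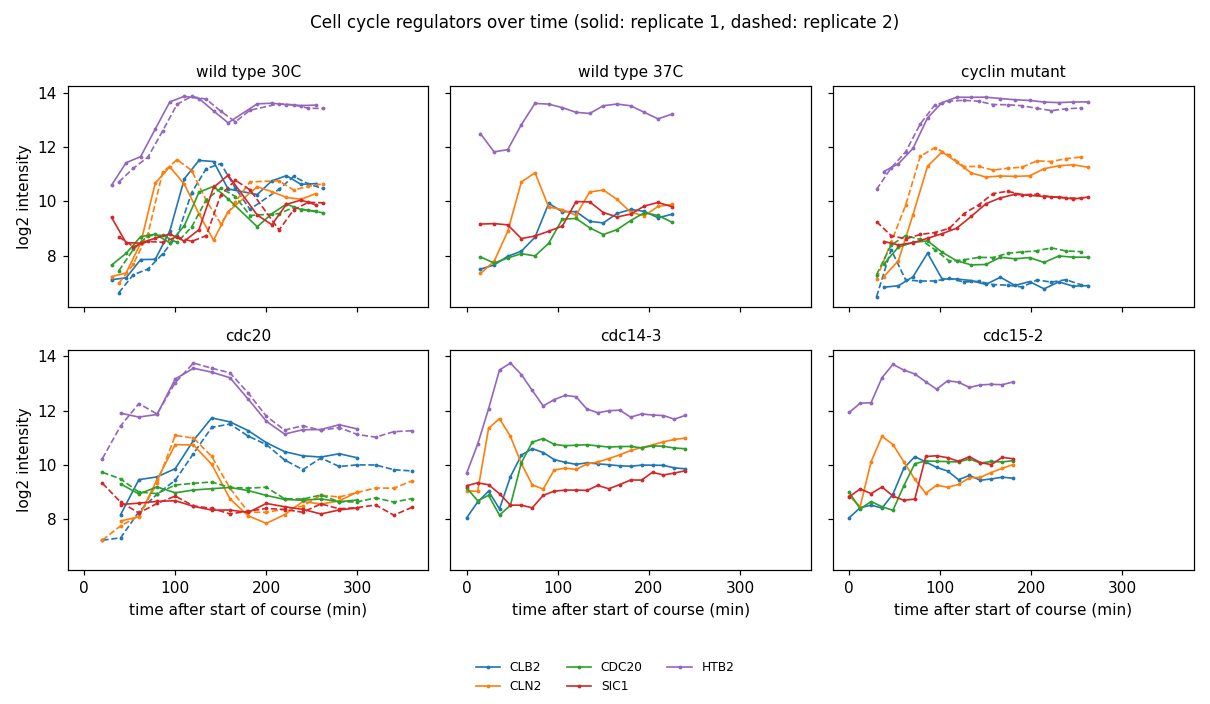
Log2 intensity (vertical axis) of CLN2, HTB2, CLB2, CDC20 and SIC1 over minutes from the start of the course (horizontal axis) in the 6 groups, replicate 2 dashed. CLB2 climbs after CLN2 in all groups but the cyclin mutant, where it stays low and its gene is disrupted per the label.

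Changes in the remaining lists over time were as follows. Pheromone genes changed in 8 of 20 members in wild type at 30 °C, 10 in wild type at 37 °C, 11 in the cyclin mutant and 16 in cdc20. Galactose genes changed in 3, 0, 4 and 5 of 5 in the same order, and in 5 in each of cdc14-3 and cdc15-2. The next counts follow the order wild type at 30 °C, at 37 °C, cyclin mutant, cdc20, cdc14-3, cdc15-2. Glucose-repressed genes changed in 5, 4, 5, 8, 8 and 7 of 10 and phosphate starvation genes in 8, 6, 6, 8, 3 and 3 of 9. DNA damage genes changed in 1, 2, 2, 2, 2 and 2 of 7 and alpha-cell markers in 2, 0, 1, 2, 1 and 0 of 4. Of the 17 ribosomal protein genes, 0 passed in any group by limma with its minimum range.

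The order of the lists at their peaks had no test. In wild type at 30 °C the means lay after the MBF targets by -0.10 min for SBF targets (17 members, circular SD 4.39 min), 13.5 min for S/G2 genes, and 14.7 min for histones (7, 2.36 min). The lag was 43.5 min for the CLB2 cluster (5, 6.87 min) and -23.4 min for Mcm1 genes. In the cyclin mutant SBF targets lay at 1.48 min, histones at 25.0 min, S/G2 genes at 33.7 min (4 members) and Mcm1 genes at -16.8 min. There the CLB2 cluster at 28.6 min had a circular SD of 34.0 min. In cdc20 SBF targets lay at 3.03 min, S/G2 genes at 10.3 min (5 members), histones at 21.3 min and Mcm1 genes at -22.4 min. No phase is given for the CLB2 cluster of cdc20 or for the other 3 groups.

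The galactose genes stood high at the start of the alpha-factor courses. GAL1 was at 14.4 at 0 min in both cdc14-3 (range 2.99, adjusted p = 1.7e-17) and cdc15-2 (range 2.62, adjusted p = 1.4e-09), and fell to 11.4 and 11.8 at the last sample. GAL2, the galactose importer, went from 13.9 to 8.67 in cdc14-3 and from 14.1 to 9.04 in cdc15-2. In the cdc20 mutant, whose label lists a GAL-driven CDC20, GAL1 fell from 13.9 and GAL10, an epimerase, from 13.1. The mean over the 5 genes was 13.41 at 0 min and 9.69 at 204 min in cdc14-3, and 13.36 and 9.97 at 180 min in cdc15-2, while the labels give dextrose medium.

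**Figure D4:**
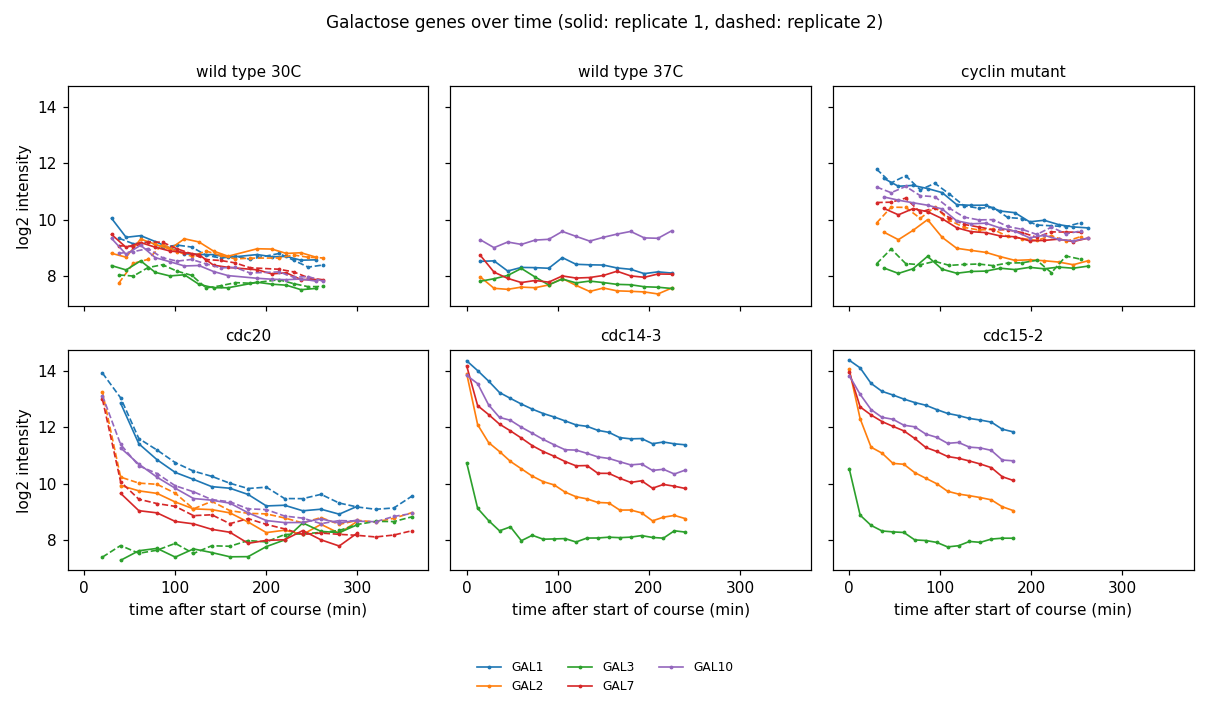
Log2 intensity (vertical axis) of GAL1, GAL2, GAL3, GAL7 and GAL10 over minutes from the start of the course (horizontal axis) in the 6 groups. All 5 go down in cdc14-3 and cdc15-2, and GAL1, GAL2, GAL7 and GAL10 in cdc20, where GAL3 goes up; most of the 5 also go down in wild type at 30 °C and the cyclin mutant, by less than in cdc14-3 and cdc15-2.

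Late in the course (100 min or later), the cyclin mutant held less mRNA of 13 of 20 CLB2 cluster genes than wild type at 30 °C (2 courses each). CLB2 was lower by -3.63 ± 0.18 (7.00 against 10.6, adjusted p = 6.6e-05) and CLB3, an early mitotic cyclin, by -3.52 ± 0.10 (adjusted p = 9.9e-06). Both genes are disrupted in this mutant per its label, so their low values can come from the disruption itself. CLB2 is counted among the 13. HOF1 was lower by -2.94 ± 0.15, DSE4 by -2.92 ± 0.12 and ASH1, a repressor in daughters, by -2.10 ± 0.10. Of the mating genes MFA2 was lower by -3.24 ± 0.12 (adjusted p = 3.2e-05) and FAR1 by -2.59 ± 0.17, as was MCM7, a replication helicase part, by -2.44 ± 0.16. Of the SBF targets 9 of 18 were higher, among them CLN2 by 1.07 ± 0.18 (adjusted p = 0.0107), CLN1 by 1.22 ± 0.13 and SVS1 by 1.23 ± 0.14, and so were 15 of 20 heat shock genes, among them HSP42 by 1.88 ± 0.12 and HSP104 by 1.27 ± 0.10.

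Of the other disrupted cyclins, CLB4 was at -2.20 ± 0.10 and CLB6 at -1.01 ± 0.16. CLB5 was at 0.68 ± 0.15 (adjusted p = 0.0244), and CLB1, which the label also lists behind the GAL1 promoter, at 0.30 ± 0.11 (adjusted p = 0.10). The values of CLB5 and CLB1 are not those of a lost transcript, and which part of these genes is disrupted is not given in the sources used here. The largest rises were SNL1, a membrane co-chaperone (3.43 ± 0.13, adjusted p = 3.2e-05), YIL014C-A (2.62 ± 0.15), and UBC13, of DNA repair (2.54 ± 0.14). Next were HXT2, a glucose importer (2.46 ± 0.28), BAR1, the alpha-factor protease (2.43 ± 0.20), and GPM2 (2.35 ± 0.12). The label of wild type lists a bar1 mutation and that of this mutant does not, so the BAR1 value is not assigned to the cyclin mutations. They were followed by TMA10 (2.01 ± 0.16), TIR3, a wall mannoprotein (2.00 ± 0.19), and PRM5, a wall stress gene (2.00 ± 0.13). Against the same wild type, UBC13 and PRM5 also rose in cdc20, and GPM2 and TMA10 in the warmer wild type, as given below. The rises of these genes are thus not specific to the cyclin mutant. Further falls were YMR030W-A (-2.50 ± 0.12), DSE2 (-2.47 ± 0.14), YGP1, a secreted stress protein (-2.44 ± 0.18), CDC20 (-1.74 ± 0.11), MCM5 (-1.61 ± 0.16) and SWI5 (-1.19 ± 0.16).

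The CLB2 cluster had 0 higher and 13 lower of 20 genes (18 when adjusted over the list alone). Mcm1 genes had 0 and 8 of 9 (8), pheromone genes 2 and 6 of 20 (8) and ribosome biogenesis 0 and 4 of 34 (4). Heat shock genes had 15 higher and 0 lower of 20 (17), stress genes 12 and 0 of 21 (15) and SBF targets 9 and 0 of 18 (13). S/G2 genes had 4 and 0 of 13 (4), galactose genes 4 and 0 of 5 (4) and MBF targets 3 and 1 of 31 (2). For glucose-repressed genes it was 2 and 1 of 10 (3), for histones 1 and 0 of 7 (1), and for DNA damage genes 1 and 0 of 7 (1). Phosphate starvation genes had 0 and 1 of 9 (3), alpha-cell markers 0 of 4 (2) and ribosomal proteins 0 of 17 (0). As whole lists, camera placed the CLB2 cluster down with an adjusted p of 4.2e-11 (adjusted p = 0.245 with an estimated correlation). It placed Mcm1 genes down with 9.1e-09 (0.127) and ribosome biogenesis down with 0.000186 (0.449). Heat shock genes lay up with 1.3e-11 (adjusted p = 0.0765 with an estimated correlation), stress genes with 9.4e-08 (0.384), galactose genes with 0.000123 (0.352) and SBF targets with 0.000186 (0.384).

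By limma 836 genes differed late, 475 higher and 361 lower, and 259 over all samples in place of the late ones. The count was 205 and 245 without replicates 1 and 2 of wild type at 30 °C, 349 without replicate 1 of the cyclin mutant, and 1277 without either course of cdc20, which enters through the shared spread.

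In cdc20 against wild type at 30 °C (2 courses each) CLB2 did not differ by the test late in the course, while all 7 measured histones were lower. The cdc20 courses ran to 300 and 360 min and those of wild type to 254 and 262 min. Part of a difference can thus come from times sampled only in cdc20. CLB2 was at -0.12 (adjusted p = 0.618) and CDC5 at 0.039 (adjusted p = 0.823). SIC1 was lower by -1.25 ± 0.11 (adjusted p = 0.000556), and EGT2, a separation enzyme, by -2.48 ± 0.14. DSE4 was lower by -2.47 ± 0.12, DSE1 by -2.44 ± 0.12 and AMN1, which resets the cycle after mitosis, by -2.27 ± 0.12. HTB2 was lower by -1.41 ± 0.12 (adjusted p = 0.000482), CLN2 by -1.10 ± 0.18 and RNR1 by -1.23 ± 0.12, while SPO12, of mitotic exit, was higher by 1.54 ± 0.14 and SWI5 by 0.85 ± 0.16.

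Further falls were YLR415C, of unknown function (-5.15 ± 0.23, adjusted p = 0.00011), YKR104W (-3.76 ± 0.23), and STB3, a ribosome regulator (-2.57 ± 0.17). YLR415C and YKR104W were also lower in the warmer wild type against the same reference, as given below. Their falls are thus not specific to cdc20, and the cause was not tested. Smaller falls were SSA4 (-1.70 ± 0.11), CSI2 (-1.57 ± 0.11), YOX1 (-1.43 ± 0.19), and PCL1 (-1.31 ± 0.13). UTP22, of ribosome assembly (-0.98 ± 0.12), was lower too, and CDC20 itself (-0.78 ± 0.11, adjusted p = 0.00234). Rises were UBC13 (2.96 ± 0.14, adjusted p = 0.00011), URA3, a pyrimidine gene and marker in the label (2.96 ± 0.14), and PRM5 (2.47 ± 0.13). AFI1 (2.45 ± 0.13), NCA3 (2.41 ± 0.16) and AFB1, a barrier to the mating factor of the other type (2.09 ± 0.12), came next. Then came ATG33 (1.94 ± 0.20), PUF3, an RNA-binding protein (1.94 ± 0.27), and CPS1 (1.90 ± 0.24), with AFR1, of mating (1.73 ± 0.12), SOL4 (1.53 ± 0.22) and HSP12 (1.13 ± 0.10). UBC13 and PRM5 were also among the rises of the cyclin mutant against the same wild type, so their rises are not specific to cdc20.

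Histones had 0 higher and 7 lower of 7 (7 when adjusted over the list alone). SBF targets had 1 and 10 of 18 (13) and MBF targets 5 and 8 of 31 (13). Among other lists, ribosome biogenesis had 1 and 16 of 34 (18), heat shock 3 and 12 of 20 (15) and S/G2 genes 1 and 3 of 13 (3). The CLB2 cluster had 8 higher and 2 lower of 20 (10), pheromone genes 8 and 2 of 20 (11) and stress genes 6 and 0 of 21 (6). There were fewer for galactose genes, 2 and 0 of 5 (2), Mcm1 genes, 2 and 2 of 9 (5), and glucose-repressed genes, 2 and 3 of 10 (5). DNA damage genes had 1 and 1 of 7 (2), alpha-cell markers 0 and 1 of 4 (1), and phosphate starvation and ribosomal protein genes 0 (0). Camera's adjusted p was 2.5e-06 for ribosome biogenesis (adjusted p = 0.416 with an estimated correlation). With 0.416 as well, it was 7.2e-05 for SBF targets and histones and 0.018 for heat shock, all 4 lists down, and 0.0497 for pheromone genes up. Ribosomal proteins lay down with 0.0479 (adjusted p = 0.673 with an estimated correlation) and stress genes up with 0.046 (0.722). With the replicate number as a block, camera's adjusted p was 0.0507 for pheromone genes, 0.0507 for ribosomal proteins and 0.0583 for stress genes, so these 3 did not pass.

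By limma 2307 genes differed, 1418 higher and 889 lower; without replicates 1 and 2 of wild type at 30 °C, 1044 and 867. The TDH1 3'-to-5' difference was also larger in cdc20 than in the other groups. Samples were taken every 20 min in cdc20 and mostly every 16 min in wild type at 30 °C. Array series and RNA work go with group, so part of these differences can come from them.

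Against wild type at 37 °C (1 course each), cdc14-3 late in the course held more mRNA of 16 of 20 pheromone genes and of 6 of 20 CLB2 cluster genes. AGA1, which anchors the mating agglutinin, was higher by 3.24 ± 0.24 (adjusted p = 0.000724), and FIG2 by 2.87 ± 0.28. FUS1, of cell fusion, was higher by 2.04 ± 0.15 and CDC20 by 1.45 ± 0.16 (adjusted p = 0.00474), while CLB2 was at 0.49 (adjusted p = 0.244). DSE2 was lower by -4.33 ± 0.20 (adjusted p = 6.5e-05), DSE1 by -4.30 ± 0.17, CTS1 by -2.42 ± 0.19 and HTB2 by -1.36 ± 0.16 (adjusted p = 0.00614). PHO84 was lower by -5.36 ± 0.16 (7.35 against 12.7, adjusted p = 8.2e-06) and GAL1 higher by 3.42 ± 0.16.

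Other rises were YGR109W-A (5.97 ± 0.15, adjusted p = 5.7e-06), YIL082W-A (3.81 ± 0.18) and YGR109W-B (3.42 ± 0.15), all genes of retrotransposons. Mating genes among them were FIG1 (2.76 ± 0.17) and PRM1, of membrane fusion (2.72 ± 0.15). Next were YPS3 (2.44 ± 0.32), GAL7 (2.21 ± 0.19), YOX1 (1.76 ± 0.26), and SVS1 (1.75 ± 0.19). Smaller rises were HSP26, a small chaperone (1.61 ± 0.18), GAL2 (1.59 ± 0.34) and JEN1, a lactate importer (1.51 ± 0.26). Other falls were DSE4 (-3.57 ± 0.17), EGT2 (-3.29 ± 0.20), YDR034C-A (-2.78 ± 0.31), SPL2 (-2.56 ± 0.42), PCL9, a cyclin of late mitosis (-2.41 ± 0.17), and DSE3 (-2.39 ± 0.20).

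Pheromone genes had 16 higher and 0 lower of 20 (18 when adjusted over the list alone), the CLB2 cluster 6 and 0 of 20 (12) and SBF targets 6 and 1 of 18 (10). For galactose genes it was 4 and 0 of 5 (4), for phosphate starvation genes 0 and 5 of 9 (5) and for histones 0 and 3 of 7 (7). Heat shock genes had 2 higher of 20 (2), S/G2 genes 1 and 1 of 13 (4) and MBF targets 1 and 1 of 31 (2). Alpha-cell markers had 1 higher of 4 (1), glucose-repressed genes 1 of 10 (1) and DNA damage genes 1 of 7 (2). Mcm1 genes had 0 of 9 (3), stress, ribosome biogenesis and ribosomal protein genes 0 (0). Camera placed pheromone genes up with an adjusted p of 2.2e-18 (adjusted p = 0.0861 with an estimated correlation). With an adjusted p of 0.333 each under an estimated correlation, it placed the CLB2 cluster up with 2.7e-08, galactose genes up with 3.2e-06, histones down with 2.9e-05, Mcm1 genes up with 0.0317 and heat shock up with 0.0484. Phosphate starvation genes lay down with 0.000185 (adjusted p = 0.477 with an estimated correlation), stress genes up with 0.00591 (0.625) and SBF targets up with 0.00992 (0.551).

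By limma 387 genes differed, 209 higher and 178 lower, and 113 without either course of wild type at 30 °C and 1044 without either course of cdc20. Alpha-factor release and array series part cdc14-3 and cdc15-2 from this elutriated wild type along with the mutations.

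The same comparison for cdc15-2 (1 course each) gave AGA1 at 3.45 ± 0.24, FIG2 at 3.11 ± 0.28 and FUS1 at 2.18 ± 0.15, all higher. It gave DSE2 at -4.19 ± 0.20 and DSE1 at -4.14 ± 0.17 (adjusted p = 3.3e-05), both lower. GAL1 was higher by 3.91 ± 0.16 (adjusted p = 3.3e-05) and PHO84 lower by -5.09 ± 0.16 (adjusted p = 1.2e-05). CDC20 was higher by 0.90 ± 0.16 (adjusted p = 0.0314), CLB2 was at 0.043 (adjusted p = 0.936) and SIC1 at 0.50 (adjusted p = 0.105). HTA1, a histone, was lower by -1.27 ± 0.19 (adjusted p = 0.0172) and NRM1 by -1.48 ± 0.17.

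Other rises were YGR109W-A (5.59 ± 0.15, adjusted p = 9.2e-06), YIL082W-A (3.46 ± 0.18), and YGR109W-B (3.22 ± 0.15). Next were PRM1 (2.65 ± 0.15), GAL7 (2.60 ± 0.19), FIG1 (2.50 ± 0.17) and PRM2 (2.38 ± 0.21). Smaller rises were JEN1 (1.66 ± 0.26) and CRH1, a wall enzyme (1.24). Other falls were YGR035C (-2.57 ± 0.17), SPL2 (-2.48 ± 0.42), DSE4 (-2.40 ± 0.17), and HUG1 (-2.13 ± 0.18). They were followed by CIS1 (-2.11 ± 0.30), SCW11, a separation glucanase (-2.08 ± 0.17), TOS6 (-1.94 ± 0.14), CSI2 (-1.25 ± 0.16) and HSP26 (-0.95 ± 0.18).

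Pheromone genes had 13 higher and 0 lower of 20 (16 when adjusted over the list alone) and galactose genes 4 and 0 of 5 (4). Phosphate starvation genes had 0 and 4 of 9 (6) and histones 0 and 3 of 7 (5). Of the other cell cycle lists SBF targets had 1 and 3 of 18 (11), MBF targets 1 and 1 of 31 (7) and the CLB2 cluster 1 and 0 of 20 (3). Alpha-cell markers had 1 higher of 4 (1), glucose-repressed genes 1 higher of 10 (1), heat shock 1 lower of 20 (1) and DNA damage 1 lower of 7 (2). S/G2 genes had 0 of 13 (1), Mcm1 genes 0 of 9 (5), and ribosome biogenesis, stress and ribosomal protein genes 0 (0). Camera's adjusted p was 1.5e-19 for pheromone genes up (adjusted p = 0.0785 with an estimated correlation), 7.1e-07 for galactose up (0.358), and 3.2e-06 for phosphate starvation down (0.543). It was 0.000182 for histones down (0.543), 0.00213 for Mcm1 genes up (0.358) and 0.00542 for ribosome biogenesis up (0.733).

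By limma 215 genes differed, 93 higher and 122 lower. Without either course of wild type at 30 °C 76 did, and without either course of cdc20 734.

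Wild type at 37 °C held more stress mRNA late than wild type at 30 °C (1 against 2 courses). HSP12 was higher by 3.69 ± 0.12 (adjusted p = 2e-05), SOL4, a sugar lactonase, by 4.40 ± 0.26, and RGI1, of respiratory growth, by 4.37 ± 0.32. HSP26 was higher by 3.03 ± 0.16, GPH1, which breaks down glycogen, by 3.56 ± 0.16 and TSL1, of trehalose synthesis, by 3.36 ± 0.31. Ribosome biogenesis was lower, with RPA135, a subunit of RNA polymerase I, at -1.41 ± 0.16 and NSR1 at -1.21 ± 0.12. HUG1 was higher by 2.70 ± 0.16, DSE2 by 1.31 ± 0.17 and SPO12 by 1.23 ± 0.17, and CLB2 lower by -1.13 ± 0.22 (adjusted p = 0.00443).

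Other rises were GPM2 (4.23 ± 0.14, adjusted p = 2e-05), TMA10 (3.88 ± 0.19), and HSP30, a membrane stress protein (3.64 ± 0.14). Next were CYC7, a cytochrome c (3.49 ± 0.24), GPG1 (3.31 ± 0.22), HSP42 (2.93 ± 0.15) and HSP104 (1.49 ± 0.12). Other falls were YLR415C (-5.41 ± 0.28), YKR104W (-3.80 ± 0.28), YLR162W (-3.66 ± 0.23) and YBL005W-A (-3.58 ± 1.24, adjusted p = 0.0446). Next were YBL112C (-3.15 ± 0.38) and YEL076C-A (-3.08 ± 0.58). Genes of known function were SAE2, of DNA end repair (-2.73 ± 0.24), HMS2 (-2.51 ± 0.15), PHO11, a phosphatase (-2.14 ± 0.33) and ASF1, a histone chaperone (-1.48 ± 0.13). Against the same reference, YLR415C and YKR104W were also lower in cdc20, and GPM2 and TMA10 also higher in the cyclin mutant.

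Stress genes had 19 higher and 0 lower of 21 (19 when adjusted over the list alone) and heat shock 10 and 3 of 20 (13). Ribosome biogenesis had 0 and 25 of 34 (26) and MBF targets 3 and 8 of 31 (11). SBF targets had 1 and 6 of 18 (6), the CLB2 cluster 1 and 6 of 20 (3), phosphate starvation genes 0 and 5 of 9 (5) and Mcm1 genes 0 and 4 of 9 (4). Pheromone genes had 7 and 4 of 20 (11), glucose-repressed 3 and 4 of 10 (7) and S/G2 genes 3 and 3 of 13 (6). Galactose genes had 1 and 2 of 5 (3), alpha-cell markers 1 and 2 of 4 (3), DNA damage genes 2 and 0 of 7 (1), and histones and ribosomal proteins 0 (0). Camera's adjusted p was 9.5e-09 for ribosome biogenesis down and 5.2e-08 for stress genes up. It was 0.0178 for phosphate starvation down, 0.0185 for SBF targets down and 0.0273 for heat shock up (each of the 5 lists adjusted p = 0.85 with an estimated correlation). By limma 2803 genes differed, 1587 higher and 1216 lower, and growth medium and study part these groups along with temperature.

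In the cyclin mutant the fitted oscillation of several separation and mitotic genes was smaller than in wild type at 30 °C and that of several replication genes larger (2 courses each). The fits used 140 min in the mutant and 110 min in wild type, so a difference can also come from how well each period suits a gene. DSE4 had a mean peak-to-trough of 0.22 against 2.15 (difference -1.93 ± 0.073, adjusted p = 0.000841), and DSE1 0.21 against 2.16 (-1.95 ± 0.11). HOF1 had a difference of -1.47 ± 0.16, PCL9 of -1.41 ± 0.083, CLB1 of -1.28 ± 0.086, EGT2 of -1.18 ± 0.16 and CLB2 of -1.11 ± 0.13 (adjusted p = 0.0302). CLB1 and CLB2, like CLB5 below, are disrupted in the mutant per its label. MCM7 went the other way with 1.97 against 0.92 (1.052 ± 0.15, adjusted p = 0.0366), as did POL30 with 2.72 against 1.83 (0.90 ± 0.11). So did YBR071W (1.46 ± 0.16), PRI2, a primase subunit (0.65), and MCM2 (0.64). KIN3, a mitotic kinase, was at 1.01 ± 0.13 but at -0.16 when measured as the SD over time. CDC21 at 0.72 (adjusted p = 0.0865) and CDC9, the DNA ligase, at 0.57 (adjusted p = 0.0582) did not pass. Other losses were RME1 (-1.18), PRY3, a wall protein of daughters (-1.14), HST3, a histone deacetylase (-1.01), MNN1, a mannosyltransferase (-0.95), DDR2, a stress gene (-0.91) and CLB5 (-0.74).

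By limma 90 genes differed in oscillation size, 34 larger and 56 smaller. They held 1 larger and 5 smaller of the CLB2 cluster (12 when adjusted over the list alone), the smaller ones including the disrupted CLB1 and CLB2. Of the MBF targets 4 and 1 differed (17), 0 and 4 of the stress genes (17) and 2 and 0 of the Mcm1 genes (8). The count was 19 and 7 without replicates 1 and 2 of wild type at 30 °C, 2 without either course of the cyclin mutant and 270 without either course of cdc20. With the SD over time in place of the peak-to-trough it was 162, and with the replicate number as a block 186.

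In cdc20 the fitted oscillation of several cell separation genes was smaller (2 courses each). Here too the fits used 140 min in the mutant and 110 min in wild type at 30 °C. DSE1 had 0.26 against 2.16 (-1.90 ± 0.11, adjusted p = 0.00457), DSE4 a difference of -1.57 ± 0.073 (adjusted p = 0.00293), and EGT2 of -1.69 ± 0.16. CTS1 had a difference of -1.36 ± 0.10, NIS1 of -1.33 ± 0.10, and DSE3 of -1.32 ± 0.18. SIC1 had 0.18 in the mutant (-0.92 ± 0.085, adjusted p = 0.0145). Further losses were HO, the mating-type switch nuclease (-1.40), PCL9 (-1.31), AIM44, of the bud neck (-1.22), PRY3 (-1.04), ASH1 (-1.04), CLB1 (-0.84), PST1, a wall protein (-0.84), AMN1 (-0.70), NRM1 (-0.68) and MYO1, the contractile ring myosin (-0.59). Of the MBF targets, TOS4 at 0.36 (adjusted p = 0.153) and POL30 at 0.052 (adjusted p = 0.859) did not pass, while NRM1 above did. ALK1, of the CLB2 cluster, was at -1.01 and did not pass either (adjusted p = 0.0585).

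By limma 33 genes differed in oscillation size, 1 larger, IZH4, of zinc response (0.97 ± 0.091), and 32 smaller. They held 2 smaller of 20 CLB2 cluster genes (15 when adjusted over the list alone) and 1 of 31 MBF targets (17). The count was 13 and 0 without replicates 1 and 2 of wild type at 30 °C, 19 without either course of the cyclin mutant, and 15 and 116 without replicates 1 and 2 of cdc20. With all courses 933 genes had an unadjusted p under 0.05, and with the SD over time in place of the peak-to-trough the count was 1161, and 62 with the replicate number as a block.

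The small counts at 37 °C are named in full, a choice made after the values were seen. The fits used 75 min in cdc14-3, 140 min in cdc15-2 and 85 min in wild type at 37 °C. In cdc14-3 against wild type at 37 °C (1 course each) SCW10 had a smaller oscillation, 0.14 against 1.75 (-1.61 ± 0.11, adjusted p = 0.0375). CLN2 at -0.86 ± 0.26 (adjusted p = 0.815) and PIR3, a wall protein, at -0.80 (adjusted p = 0.381) did not pass. In cdc15-2 SCW10 was smaller by -1.32 ± 0.11 (adjusted p = 0.0345). YPS3 at 1.42 ± 0.11, DDR2 at 1.23 ± 0.087 (both adjusted p = 0.0303) and HXT1, a glucose importer, at 1.22 ± 0.11 were larger. CTS1 at 1.04 (adjusted p = 0.0881), CLB1 at 1.02 (adjusted p = 0.0727), NRM1 at 0.95 (adjusted p = 0.0697) and POL30 at -0.86 (adjusted p = 0.213) did not pass. Unadjusted p-values under 0.05 numbered 310 and 579, and the SD over time called 16 and 10 genes. Without any single course of wild type at 30 °C or the cyclin mutant limma called 0 genes in both comparisons, and without either course of cdc20 2 genes in each.

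At 16 matched times cdc14-3 had 9 of 21 stress genes higher than cdc15-2 (1 course each), and several cell separation genes lower. EGT2 was lower by -1.91 ± 0.15, PIR1, a wall protein, by -1.95 ± 0.18 (adjusted p = 1.9e-08), and DSE4 by -1.64 ± 0.15. AIM44 was lower by -1.68 ± 0.12, PCL9 by -1.54 ± 0.10 and DSE3 by -1.19 ± 0.097, each of the 6 genes at 16 of 16 times. TKL2, a transketolase, was higher by 2.21 ± 0.11 (adjusted p = 9.8e-12), HSP26 by 2.12 ± 0.20 (adjusted p = 3.1e-08), DDR2 by 1.38 ± 0.14 and HUG1 by 1.21 ± 0.088, also at all 16 times. SIC1 was lower by -0.62 ± 0.14 (adjusted p = 0.00061) at 13 of 16 times and HTB2 by -0.74 ± 0.14, while CLB2 at 0.38, CDC20 at 0.48 and GAL1 at -0.21 stayed under the minimum fold.

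Other rises were FMP16 (2.03 ± 0.13), EGO4 (1.71 ± 0.14), SIP18, of dehydration stress (1.28 ± 0.25), and ERR3 (1.27 ± 0.17). YBL100W-A (1.16) and YBL005W-A (1.14) followed. Smaller rises were PHO5 (0.81), RNR3, a damage-induced reductase (0.77), AGA2, the agglutinin (0.69), MOB1, of mitotic exit (0.69 ± 0.05), FUS3, the mating kinase (0.63), GAC1 (0.59) and NRM1 (0.59). Other falls were YLR154C-H (-1.87 ± 0.05, adjusted p = 3.2e-15), YFR035C (-1.49 ± 0.041), YDR034C-A (-1.27), YDR524W-C (-1.20) and CDC45, a replication factor (-0.61). Stress genes had 9 higher and 0 lower of 21, and heat shock, pheromone and DNA damage genes 2 and 0 each. MBF targets had 1 and 1, SBF targets, CLB2 cluster and phosphate starvation genes 1 and 0, histones 0 and 1, and the other lists described here 0, with the same counts over each list alone.

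By limma 186 genes differed, 99 higher and 87 lower, and 182 of them went the same way at 14 or more times. The TDH1 3'-to-5' difference of 1.00 against 1.97 parts both courses as well, and cultures and mutations are not separable with 1 course each.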

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

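The tests of galactose genes in this section were chosen after seeing the result; the tests on shuffled times and exchanged arrays were set before the data were examined. A comparison between the contrasts drew attention to the number of genes called in oscillation size, which differs between the groups compared: 90 for the cyclin mutant, 33 for cdc20, 1 for cdc14-3 and 4 for cdc15-2. Both contrasts with wild type at 37 °C have 1 course a side and those with wild type at 30 °C have 2, so the counts were made at unequal precision and are not compared as biology; the cause was not tested.

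The number of periodic genes was set against scatter with no order in time, by shuffling the sample times within each course 100 times. In wild type at 30 °C 0 of 100 shuffles called as many as the real 709 (highest 345), and in cdc15-2 0 of 100 as many as 329 (highest 7). In the cyclin mutant 3 of 100 called as many as 519 (highest 1149), below the limit set beforehand. Scatter is thus less likely there but not excluded. A single pulse can also exceed shuffled times, so the test does not show a repeat. In cdc20 6 of 100 called as many as 220, with a highest of 1381, so scatter is not excluded, and the periodic genes of cdc20 may owe part of their number to it. The shuffles of cdc20 and of the cyclin mutant that call far more than the real count point to a structure of the samples, the cause of which was not tested. For wild type at 37 °C and cdc14-3 the real count was 0 in limma, against 396 and 381 with an unadjusted p under 0.05, so 100 of 100 shuffles call as many and the test says nothing; the highest were 233 and 22.

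The differences between cdc14-3 and cdc15-2 at matched times were set against exchanges of arrays between both courses within time points. Of 100 assignments, 1, the real one, gave 186 genes, and the highest other gave 42, so an accidental assignment is excluded. This says that both cultures differ, and could as well reflect the cultures as the mutations, since each has 1 course.

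The high galactose genes at the start of cdc14-3 and cdc15-2 were weighed against 3 explanations. After quantile normalization the smaller of both median falls over the 5 genes was 3.10, against 3.03 without. It was laid over processed values and moved array medians by at most 0.22, so it cannot decide on the authors' normalization. In wild type at 37 °C the median fall was 0.393, which goes against transfer to 37 °C alone. That course was elutriated in an earlier study and first sampled at 15 min, so the comparison is not a clean one. In replicate 1 of wild type at 30 °C, the cyclin mutant and cdc20, all elutriated, the median fall was 1.48, 1.06 and 1.41. These courses were first sampled at 30, 38 and 40 min, and cdc14-3 and cdc15-2 at 0 min, so an earlier fall is not covered. The labels also list CLB1 behind the GAL1 promoter in the cyclin mutant and a GAL-driven CDC20 in cdc20. The cause of these smaller median falls was not tested. Single genes of cdc20, replicate 1, ranged from -1.27 to 3.67. Growth on a carbon source other than dextrose before release remains a candidate explanation: the glucose-repressed genes fell by a median of 0.386 more than in wild type at 37 °C in the course with the smaller fall, too little to tell. The labels give dextrose, and the medium before release is not described further in the sources used here.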

How the results depend on the processing

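The tests of galactose genes and the use of replicate 2 values as deposited were chosen after seeing the result; the other alternatives were set before. The main limits are these. The comparisons rest on 2 courses a group or 1. Those with wild type at 37 °C mix mutation with synchronisation and array series. Array series and RNA work can part cdc20 from wild type at 30 °C too. The periods of the cyclin mutant, cdc20 and cdc15-2 sit at the upper end of those tried. All results with wild type at 30 °C rest on the inferred move of replicate 2. Among the named late level differences, quantile normalization kept 472 in size and call, strengthened 15, weakened 5 and reversed 0.

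With no minimum range the genes called as changing were 4811, 4160, 5111, 5233, 4112 and 3788, in the order wild type at 30 °C, at 37 °C, cyclin mutant, cdc20, cdc14-3, cdc15-2. Leaving out samples before 30 min gave 462 changing genes in cdc14-3 and 327 in cdc15-2, and 218 periodic in cdc15-2. With no minimum peak-to-trough the periodic genes were 2112 in wild type at 30 °C, 1919 in the cyclin mutant, 406 in cdc20 and 837 in cdc15-2. A quadratic trend gave 395 periodic genes in wild type at 30 °C and, in the later window, 250 there, 90 in wild type at 37 °C and 12 in cdc20. A period 10 min longer gave 47 later genes in wild type at 37 °C and 20 in cdc20, and moved the SBF targets of the cyclin mutant to 6.27 min and the histones of cdc20 to 24.0 min after the MBF targets. A period 10 min shorter gave 124 periodic genes in cdc20 and 123 in cdc15-2, and 0 later genes in cdc20 in limma, against 595 with an unadjusted p under 0.05 at 140 min.

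Over all samples in place of the late ones, 259 genes differed between the cyclin mutant and wild type at 30 °C, and CLB1 in cdc20 turned to 0.19. From 140 min on, 349 differed between cdc15-2 and wild type at 37 °C. The replicate number as a block, although the numbers do not pair the courses, gave 131 late genes for cdc15-2, 5 list shifts for cdc20, and 186, 62 and 0 genes in oscillation size for the cyclin mutant, cdc20 and cdc14-3, the last against 310 with an unadjusted p under 0.05 in limma without the block. The SD over time in place of the peak-to-trough gave 162, 1161, 16 and 10 genes for the cyclin mutant, cdc20, cdc14-3 and cdc15-2, and KIN3 in the cyclin mutant turned to -0.16. Without the dimmest 25% of genes 111 differed at matched times, and with no minimum fold 4029. With an estimated correlation camera called 0 list shifts in each of the 5 contrasts.

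Leaving out single courses moved these counts. Periodic genes numbered 0 without replicate 1 and 0 without replicate 2 of wild type at 30 °C, 57 and 154 without those of the cyclin mutant, and 0 and 1 without those of cdc20, and later genes of cdc20 0 without its replicate 1, all in limma, where unadjusted p-values under 0.05 numbered 3060, 2566, 1556 and 595 with both. Without replicates 1 and 2 of wild type at 30 °C the late level counts were 205 and 245 for the cyclin mutant, 1044 and 867 for cdc20, 113 both times for cdc14-3 and 76 for cdc15-2, and the oscillation counts 19 and 7, 13 and 0, 0 and 0, and 0 and 0 in the same order. Without replicate 1 of the cyclin mutant its late level count was 349, without either of its courses that of cdc20 2355, and without either of its courses the oscillation counts were 2, 19, 0 and 0. Without either course of cdc20 the late level counts were 1277 for the cyclin mutant, 1044 for cdc14-3 and 734 for cdc15-2, and the oscillation counts 270, 15 without replicate 1 and 116 without replicate 2, 2 and 2.

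With replicate 2 of wild type at 30 °C as deposited, 1196 genes changed over time, 6 were periodic and 4 later. Limma then called 0 genes in all 5 late level and all 4 oscillation contrasts. After the move it called 215 to 2803 and 1 to 90 genes, and between 310 and 3144 had an unadjusted p under 0.05. Of the named late level differences 61 reversed. Against wild type at 30 °C, for the cyclin mutant these were BOP2 -0.55, TIR3 -0.52, CLN1 -0.033, CLB5 -0.0061, DUN1 -0.18, SPC34 -0.020, YHP1 -1.06, STU2 -0.71, CHS2 0.33, NOG2 1.22, RLP7 0.81, TIF6 1.55, CBF5 0.83, HSP78 -0.13, GPH1 -0.65, PCK1 -1.29, GAL10 -0.17, GAL1 -0.37, GAL7 -1.01 and GAL3 -2.36. For cdc20 these were PUF3 -0.45, EGT2 0.20, RNR1 1.07, HTB2 0.60, HTA1 1.52, HHT2 2.14, HTA2 2.17, FKH1 0.12, KIN3 -0.26, UTP10 1.65, NOG2 1.27, NSR1 1.73, HSP104 0.83, YDJ1 0.23, GPH1 -0.26, PCK1 -0.90, ICL1 0.013, GAL1 -0.94, GAL10 -0.88, DDR48 0.11, HUG1 -0.70, CLB5 -0.23 and NRM1 0.94. For wild type at 37 °C these were CSI2 0.26, AXL2 0.51, SVS1 0.68, TOS4 0.70, RNR1 1.19, YHP1 -0.82, SPC34 -0.11, MCM3 0.20, STE3 -0.0053, NSR1 1.01, RPA135 1.44, PCK1 -0.38, GAL10 -0.46, VTC3 0.37, PHO84 1.17, PHO11 0.63, VTC4 0.054 and CDC14 0.45.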

Other observations

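The tests in this section were chosen before the data were examined, while the patterns were picked after seeing the result. The Mcm1 genes, which include the MCM helicase genes beside CDC6, SWI4 and CLN3, were periodic in 9 of 9 members in the cyclin mutant. MCM3 went from 11.8 at 70 min to 8.73 at 254 min (peak-to-trough 1.49 ± 0.19, adjusted p = 1.5e-05 in limma) and MCM5 from 10.4 to 7.45 at 174 min (1.53 ± 0.23). MFA1, a mating factor gene, had 1.36 ± 0.16 (adjusted p = 3.6e-06) and went from 13.6 at 86 min to 10.1 at 230 min. In cdc20 the helicase gene MCM7 rose to 11.8 at 180 min (range 3.17), PIR3 to 12.8 at 360 min (range 4.25) and SSC1, a mitochondrial chaperone, to 13.4 at 300 min (range 2.28). The value at 360 min comes from replicate 2 only.

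A hypothesis concerns Ty3 elements, whose transcripts stood higher by 5.97 ± 0.15 (YGR109W-A) in cdc14-3 and 5.59 ± 0.15 in cdc15-2 than in wild type at 37 °C. Pheromone genes were higher there too, 16 and 13 of 20, so the arrest with alpha factor could raise both, but strain and array series differ as well; without either course of wild type at 30 °C, limma called 113 and 76 genes in these contrasts in place of 387 and 215. A course of wild type of the same background, released from alpha factor at 37 °C on the same arrays, would part the mutations from arrest and array series. It would not part the arrest from the array series.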
